A study of Mus musculus with 6 samples.

How the data were processed

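Poly-A RNA libraries were made from tissue around the gel of wild-type mice, 3 per gel, on day 7. Per the submitters' processing notes, the tools named were CASAVA, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0, with genome build mm10; their roles and order are not given in the sources used here. Whether strand was used in counting is also not given.

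The deposited signal per library is a gene count divided by 1 size factor per library, given for 1035 genes. Tested on the values, each of these genes had an adjusted p under 0.05 and an absolute log2 fold change above 0.5 in the deposited table. Both deposited tables give the authors' log2 fold change of D-Gel over L-Gel and the authors' adjusted p-value, and the table of picked genes also the unadjusted p-value. The table of all genes lists 24039 genes, of which 6530 carry an adjusted p of 1 and stand outside the adjustment, leaving 17509 tested. There, 24 names had been turned into dates and 17 names stood on more than 1 row; these were left out of the lists.

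The values of each library were whole multiples of 1 step, and dividing by it gave whole reads for 100% of values within a relative tolerance of 1e-06. Libraries of the same gel differed by more than sampling noise, with a chi-square per degree of freedom between 22.5 and 126 over genes with at least 10 reads, so none was counted as a duplicate. Intervals of read ratios are at the 95% level, and the floor is 3 reads over the 3 libraries of a group; both cover counting error only. Gene identifiers were looked up in GENCODE M21: 1034 of 1035 were found, and 1010 had the same start and end. Members of gene families such as the H2 genes may share reads, and how the counting divided these is not known.

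The design fixed before the data were examined was an edgeR quasi-likelihood test on counts, with limma-trend for normalized values. The values proved to be normalized and to cover only picked genes. Counts of changed genes are therefore the authors' calls at an adjusted p under 0.05, as the design provided for, and every refit is a test on genes chosen for the difference. The refit used limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) for genes with a mean value of at least 1, with Benjamini-Hochberg adjustment. Fold changes of the refit are on that scale and understate the change of low genes. Alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 10, edgeR 4.0.16, DESeq2 1.42.0 and limma-voom on the recovered reads with the deposited size factors, the replicate number as a block, and leaving out each library. On simulated data for this comparison over 1035 genes, limma-trend recovered 93% of 100 genes changed by 1 and 99% of 100 genes changed by 2 on the log2 scale, and called 0.838% of unchanged genes. All simulated genes had the same dispersion, which was not estimated from these libraries. The rates need not hold for genes with a wider spread between libraries.

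The unadjusted p-value of the 17509 genes in the adjustment was recovered by inverting the Benjamini-Hochberg adjustment along the row order of the deposited table. Genes with an adjusted p of 1 were given the p of the next tested row. Against the authors' unadjusted p of 1034 genes, the ratio lay between 0.997 and 1.02; all of these genes had an adjusted p under 0.05. In simulated data over 17509 genes, the ratio of recovered to true p reached 1.50 among p below 0.05, so a recovered p can be too large. The last 5 rows gave no p. Standard errors and 95% intervals implied by these p-values assume a two-sided normal test. Adjustment over a list alone used the recovered p.

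The 39 gene lists were fixed before the data were examined, and 8 more were added after. Lists were tested with limma's cameraPR on the signed normal quantile of the recovered p, with an inter-gene correlation of 0.01 and at least 5 tested members. This test was chosen after seeing the data, since camera on values per library could not cover all genes. The correlation was estimated for lists with at least 3 called members with values per library. It rests on those picked members alone and not on the whole list. The adjusted p with an estimated correlation was taken over only the lists that had an estimate. In simulated data over 17509 genes, 6 of 200 unshifted and 17 of 20 shifted lists passed an unadjusted p of 0.05. The simulated genes were independent of each other, whereas the estimated correlation here reached 0.88 for the cell proliferation list. These rates therefore do not hold for lists of correlated genes.

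The genes named were chosen by a rule fixed beforehand. It took the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with a mean of at least 100 normalized counts in the higher gel and no overlap between gels, without immunoglobulin, T-cell receptor and predicted genes. It added the 3 members of each list with the smallest p, and landmark immune and stromal genes whatever their result. Further list members named in the text were chosen after their values were seen. Some genes that the rule or the lists hold are not reported here by name. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were also used.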

Results

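Messenger RNA was sequenced from mouse tissue taken at the site of an injected polypeptide hydrogel on day 7. The gels differed in the chirality of their amino acid residues. By their names, L-Gel was built from L residues and D-Gel from the mirror-image D residues. Each was represented by 3 libraries from wild-type mice. The labels do not say whether libraries of one gel came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Values per library were given for 1035 genes that the authors had picked for their difference, and fold changes with adjusted p-values for 24039 genes. The reads behind the picked genes came to 2098825, 2159848 and 2427413 in D-Gel libraries 1 to 3 and to 1580765, 1544851 and 1590603 in L-Gel libraries 1 to 3. These sums are not the depth of the libraries, which was not analysed here. The deposited size factors lay between 0.915 and 1.11.

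The comparison of D-Gel with L-Gel asked how residue chirality changed the local immune environment of the gel. The largest falls under the naming rule were those of epithelial genes and the largest rises those of skeletal muscle genes. Of the fixed lists, keratinocyte and cell proliferation genes shifted downwards in D-Gel and skeletal muscle and MHC class I genes upwards. These shifts held with an estimated correlation, adjusted over the 15 lists that had one and not over 38. The shifts of the B-cell list downwards and of the lysosome and giant cell list upwards were lost with it (adjusted p = 0.104 and adjusted p = 0.192 with an estimated correlation, limma cameraPR). In the authors' deposited table, 657 genes were higher and 596 lower in D-Gel at an adjusted p under 0.05. Of these, 194 were higher and 299 lower by at least 1 on the log2 scale. The share of higher genes was 52.4% without a fold minimum and 39.4% with it.

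Several keratin and other epithelial genes were read in L-Gel and were at or near 0 in D-Gel, while others fell less. Krt8, a keratin of simple epithelia on chromosome 15 (101996698 to 102004482, mm10, ENSMUSG00000049382), had a normalized count of 922 ± 134 (SD, n = 3) in L-Gel and 1.30 ± 1.54 (SD, n = 3) in D-Gel. Its partner Krt18, also on chromosome 15 (102028180 to 102032027, ENSMUSG00000023043), had 598 ± 150 (SD, n = 3) in L-Gel and 2.09 ± 1.98 (SD, n = 3) in D-Gel. The authors' deposited table gave log2 fold changes of -9.44 for Krt8 (adjusted p = 5.34e-33) and -8.23 for Krt18 (adjusted p = 1.94e-34). The basal keratins Krt14 and Krt5, the transcription factor Foxa1, the secreted scavenger protein Dmbt1 and the keratin Krt17 had no read in any D-Gel library. Against a floor of 3 reads over the group, they were at least 368-fold (Krt14), 274-fold (Krt5), 104-fold (Foxa1), 339-fold (Dmbt1) and 117-fold (Krt17) lower in D-Gel. The milk protein gene Csn3 had 2 reads over the D-Gel libraries and 782 over the L-Gel libraries, a ratio of 388 with a 95% counting interval from 107 to 3208. Sfn, an epithelial 14-3-3 protein, was still read in D-Gel and fell by 1.04 on the log2 scale in the authors' deposited table (adjusted p = 0.00595). Its adjusted p in the limma-trend refit was 0.0583 without L-Gel library 2 and 0.0629 without L-Gel library 3. The counts were uneven among L-Gel libraries for Krt14, with normalized counts of 101, 545 and 458 in libraries 1 to 3. Of 10 tested members of the keratinocyte list, 7 fell, 0 rose and 3 did not pass. Adjusted over the list alone, 8 fell. The list shifted downwards (limma cameraPR, adjusted p = 2.91e-17). Krt10, a keratin of the upper epidermis, had a log2 fold change of 0.09 in the authors' deposited table (adjusted p = 0.968).

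Several B-cell genes were lower in D-Gel. Cd79a, a chain of the B-cell receptor complex, had a normalized count of 103 ± 66.0 (SD, n = 3) in L-Gel and 4.08 ± 3.64 (SD, n = 3) in D-Gel. Ms4a1, which encodes CD20, had 69.2 ± 50.3 (SD, n = 3) and 5.44 ± 3.14 (SD, n = 3). The authors' deposited table gave log2 fold changes of -4.62 for Cd79a (adjusted p = 2.19e-08), -3.65 for Ms4a1 (adjusted p = 2.35e-05) and -3.07 for the transcription factor Pax5 (adjusted p = 4.74e-05). Of 12 tested members of the B-cell list, 6 fell, 1 rose (Cd22) and 5 did not pass. Adjusted over the list alone, 7 fell and 1 rose. The shift of the list (limma cameraPR, adjusted p = 1.18e-06) was lost under a gene correlation taken from the values (adjusted p = 0.104 with an estimated correlation). In L-Gel library 1, Cd79a had a normalized count of 30.3, against 159 and 121 in libraries 2 and 3. Of 13 plasma cell genes, 2 fell (Igkc and Mzb1), 1 rose (Irf4) and 10 did not pass, with the same counts adjusted over the list alone. In the limma-trend refit, the adjusted p of Irf4 was 0.0821 without D-Gel library 1, 0.0777 without L-Gel library 2 and 0.0799 without L-Gel library 3, and that of Igkc was 0.0547 without L-Gel library 2.

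Most cell proliferation genes tested fell. Birc5, an inhibitor of apoptosis needed for cell division, on chromosome 11 (117849251 to 117855743), had a normalized count of 217 ± 64.5 (SD, n = 3) in D-Gel and 537 ± 38.4 (SD, n = 3) in L-Gel. Mki67, the proliferation marker, had 1554 ± 564 (SD, n = 3) and 2650 ± 461 (SD, n = 3). The authors' deposited table gave log2 fold changes of -1.31 for Birc5 (adjusted p = 1.22e-06), -1.23 for Ube2c (adjusted p = 1.41e-06), -1.18 for Rrm2 (adjusted p = 7.43e-06) and -0.77 for Mki67 (adjusted p = 0.0209). Of 20 tested members of the list, 16 fell, 0 rose and 4 did not pass, and 19 fell when adjusted over the list alone. The list shifted downwards (limma cameraPR, adjusted p = 8.49e-23). In the limma-trend refit, fitted and adjusted over all picked genes, 16 of the 16 members with values per library passed with all libraries. All of these had been picked for their difference. Without L-Gel library 3, 9 passed. The refit's adjusted p for Mki67 was 0.061 without L-Gel library 2 and 0.0658 without L-Gel library 3.

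Skeletal muscle genes were higher in D-Gel, and unevenly so among its libraries. Ckm, the muscle creatine kinase on chromosome 7 (19404776 to 19422841), had normalized counts of 16, 442 and 302 in D-Gel libraries 1 to 3. Its reads over the group were 754 in D-Gel and 2 in L-Gel, a ratio of 380 with a 95% counting interval from 105 to 3145. Myh4, a fast myosin heavy chain, had 960 reads against 1, a ratio of 968 with a 95% counting interval from 173 to 38273. Pvalb, a calcium-binding protein of fast fibres, was not read in L-Gel and was at least 139-fold higher in D-Gel. The authors' deposited table gave log2 fold changes of 7.34 for the calcium pump Atp2a1 (adjusted p = 2.1e-07), 6.65 for Myh1 (adjusted p = 9.58e-05), 6.31 for titin, Ttn (adjusted p = 0.0186), and 6.11 for Myl1 (adjusted p = 5.95e-05). Myh8, a perinatal myosin, had 348 reads in D-Gel and 3 in L-Gel, a ratio of 117 with a 95% counting interval from 39.7 to 570. Most of the Myh8 reads came from 1 library, with normalized counts of 3.00, 50.3 and 270 in D-Gel libraries 1 to 3. Without L-Gel library 1, its adjusted p in the limma-trend refit was 0.0517. Of 14 tested members of the muscle list, 13 rose, 0 fell and 1 did not pass, and 14 rose when adjusted over the list alone. The list shifted upwards (limma cameraPR, adjusted p = 7.73e-24).

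Several phagocyte and lysosomal genes rose in D-Gel while the scavenger receptors Cd36 and Marco fell. Gpnmb, a glycoprotein of lipid-laden macrophages and giant cells on chromosome 6 (49036546 to 49070929, ENSMUSG00000029816), had a normalized count of 258089 ± 35274 (SD, n = 3) in D-Gel and 134625 ± 17588 (SD, n = 3) in L-Gel. Itgax, which encodes CD11c, on chromosome 7 (128129547 to 128150657, ENSMUSG00000030789), had 6017 ± 340 (SD, n = 3) in D-Gel and 2582 ± 357 (SD, n = 3) in L-Gel. The authors' deposited table gave log2 fold changes of 0.94 for Gpnmb (adjusted p = 4.15e-08), 1.22 for Itgax (adjusted p = 1.95e-16), 1.36 for the beta-glucan receptor Clec7a (adjusted p = 1.05e-15) and 0.85 for the protease Ctss (adjusted p = 6.13e-07). The scavenger receptors went the other way in the authors' deposited table: Cd36 had a log2 fold change of -1.12 (adjusted p = 3.18e-11) and Marco one of -3.82 (adjusted p = 0.000341). Marco was little read, with a normalized count of 2.46 ± 2.61 (SD, n = 3) in D-Gel and 33.6 ± 17.4 (SD, n = 3) in L-Gel. Cd36 had 17750 ± 2944 (SD, n = 3) in D-Gel and 38480 ± 3180 (SD, n = 3) in L-Gel. Of 18 tested members of the lysosome and giant cell list, 6 rose, 0 fell and 12 did not pass, and 9 rose when adjusted over the list alone. Its shift upwards (limma cameraPR, adjusted p = 6.42e-07) was lost under a correlation taken from only 3 picked members (adjusted p = 0.192 with an estimated correlation). Of 15 macrophage genes, 3 rose (Gpnmb, also in the lysosome and giant cell list, Cd68 and Mertk), 1 fell (Marco) and 11 did not pass, and adjusted over the list alone 5 rose and 2 fell. Its test was positive (limma cameraPR, adjusted p = 0.0464), its median log2 fold change 0.08 and its mean -0.07, and the call was lost (adjusted p = 0.483 with an estimated correlation). Of 15 dendritic cell genes, 4 rose (Itgax, Irf8, Xcr1 and Cd209a), 0 fell and 11 did not pass, with 5 rising when adjusted over the list alone. The shift (limma cameraPR, adjusted p = 0.000382) was lost as well (adjusted p = 0.11 with an estimated correlation). Of 17 scavenger and Fc receptors, 1 rose, 2 fell and 14 did not pass, and 2 rose and 2 fell when adjusted over the list alone. This list did not shift (limma cameraPR, adjusted p = 0.995).

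**Figure D1:**
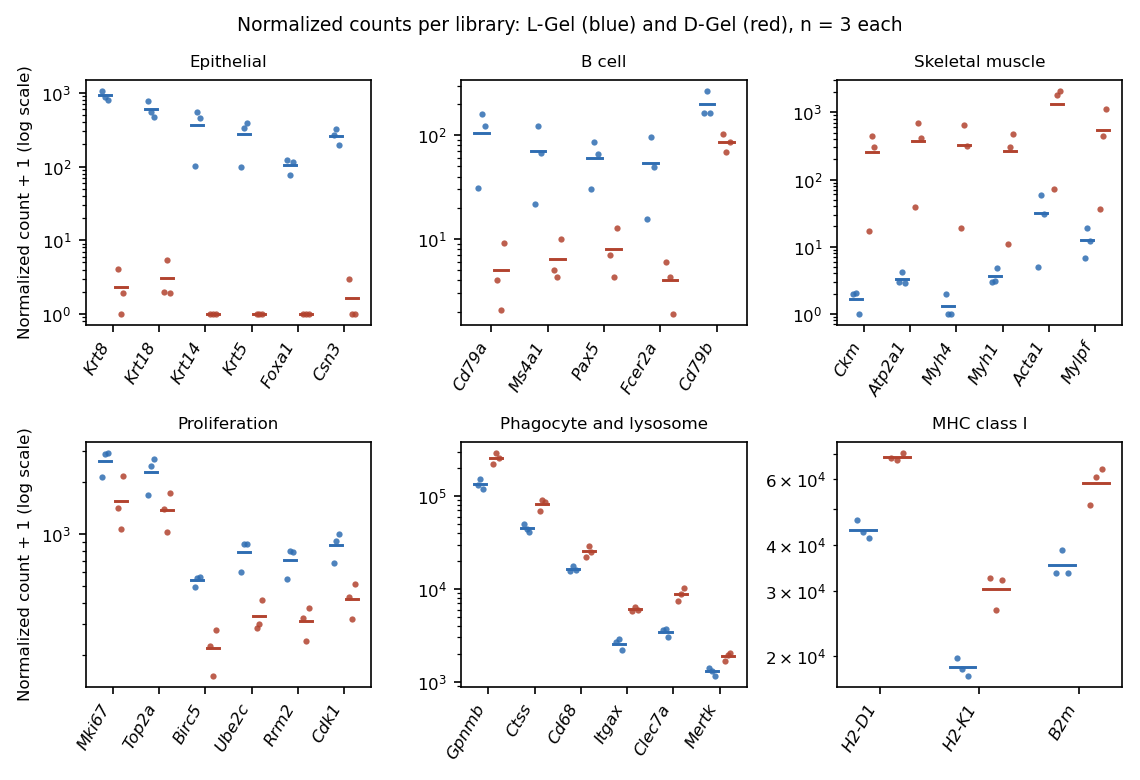
Normalized count plus 1 (log axis) of selected genes in each library of L-Gel (blue points) and D-Gel (red points), with a bar at the mean of the 3 libraries of a gel. Krt14 lay at 0 normalized counts in each D-Gel library, and Ckm lay at 16, 442 and 302 in D-Gel libraries 1 to 3.

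Several MHC class I genes rose. H2-D1 had a normalized count of 69054 ± 1532 (SD, n = 3) in D-Gel and 43808 ± 2486 (SD, n = 3) in L-Gel, and B2m, the light chain of the complex, 58634 ± 6773 (SD, n = 3) and 35220 ± 3019 (SD, n = 3). The authors' deposited table gave log2 fold changes of 0.66 for H2-D1 (adjusted p = 8.29e-09), 0.70 for H2-K1 (adjusted p = 1.05e-06) and 0.74 for B2m (adjusted p = 2.25e-06). H2-D1 and H2-K1 are close paralogs, so reads may have been divided between them. Of 12 tested members of the class I list, 4 rose, 0 fell and 8 did not pass, and 5 rose when adjusted over the list alone. The list shifted upwards (limma cameraPR, adjusted p = 1.45e-08), which was lost with the log2 fold change as the statistic (adjusted p = 0.337). Of 12 class II genes, 1 rose (the protease Ctss, also in the lysosome and giant cell list), 0 fell and 11 did not pass, with the same counts adjusted over the list alone. That list also shifted upwards (limma cameraPR, adjusted p = 0.0112), and its call was lost in the same way (adjusted p = 0.487). In the authors' deposited table H2-Ab1 had a log2 fold change of 0.36 (adjusted p = 0.515).

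Some complement genes were higher. In the authors' deposited table, C3 had a log2 fold change of 1.70 (adjusted p = 0.00984), Serping1 one of 0.72 (adjusted p = 0.0012) and C5ar1 one of -0.72 (adjusted p = 0.0156). Of 18 tested members, 6 rose, 1 fell and 11 did not pass, and 8 rose and 1 fell when adjusted over the list alone. The shift (limma cameraPR, adjusted p = 0.000573) was lost (adjusted p = 0.11 with an estimated correlation). Without L-Gel library 3 the adjusted p of C5ar1 in the limma-trend refit was 0.0629. Chemokine genes were more often lower: of 28 tested, 6 fell, 2 rose and 20 did not pass, and 8 fell and 2 rose when adjusted over the list alone. The 6 that fell include Pf4 and Ppbp, which are also the 2 falling members of the platelet list. The authors' deposited table gave log2 fold changes of -1.39 for Cxcl2 (adjusted p = 8.14e-05), -1.73 for Pf4 (adjusted p = 0.00178) and 1.01 for Ccl22 (adjusted p = 0.000482). The chemokine shift (limma cameraPR, adjusted p = 0.0173) was lost (adjusted p = 0.483 with an estimated correlation).

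Several myofibroblast and pericyte genes fell. The authors' deposited table gave log2 fold changes of -1.24 for Lrrc15 (adjusted p = 0.000127), -1.11 for Cspg4 (adjusted p = 0.012), -0.89 for Acta2 (adjusted p = 0.0203) and 1.12 for desmin, Des (adjusted p = 0.00679). Des is also a gene of skeletal muscle, whose list had 13 of 14 members higher in D-Gel, and its normalized counts were 555, 715 and 1463 in D-Gel libraries 1 to 3. Of 10 tested myofibroblast and pericyte genes, 4 fell, 1 rose and 5 did not pass, and 6 fell and 1 rose when adjusted over the list alone. The shift downwards (limma cameraPR, adjusted p = 0.000735) was lost (adjusted p = 0.11 with an estimated correlation). Of the 5 members among the picked genes, 4 fell and 1 rose in the limma-trend refit of all picked genes with all libraries. Without L-Gel library 1 or without L-Gel library 3, 2 fell and 0 rose. Without library 3, the adjusted p in that refit was 0.0823 for Des, 0.0675 for Cspg4 and 0.0769 for Acta2, and without L-Gel library 1 it was 0.0517 for Des and 0.0619 for Cspg4. Acta2 had 0.102 without L-Gel library 2 and 0.0783 without D-Gel library 2. Fibroblast genes showed no list shift (limma cameraPR, adjusted p = 0.191): of 17 tested, 2 fell (Thy1 and Lum), 1 rose (Pi16) and 14 did not pass, with the same counts adjusted over the list alone. Col1a1, the main collagen chain, had a log2 fold change of -0.01 in the authors' deposited table (adjusted p = 0.99). Of 13 endothelial genes 1 rose, 1 fell and 11 did not pass, and 1 rose and 3 fell when adjusted over the list alone. Vwf, the von Willebrand factor gene, had a log2 fold change of 1.37 in the authors' deposited table (adjusted p = 1.43e-14) and the junction gene Esam one of -0.83 (adjusted p = 0.00919), and the median of the list was -0.61.

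T-cell genes did not shift (limma cameraPR, adjusted p = 0.652): of 19 tested, 1 rose (Cd28), 0 fell and 18 did not pass, and 2 rose when adjusted over the list alone. In the authors' deposited table, Cd28 had a log2 fold change of 1.52 (adjusted p = 2.98e-06), Cd4 one of 1.71 (adjusted p = 0.0598), Cd8a one of -0.96 (adjusted p = 0.254) and Cd3e one of -0.29 (adjusted p = 0.917). The cytotoxic lymphocyte list shifted upwards (limma cameraPR, adjusted p = 0.0128), although 0 of 16 tested members passed alone, 3 of them at an unadjusted p under 0.05. That shift was lost in limma cameraPR with a preset correlation of 0.05 (adjusted p = 0.0644) and with the log2 fold change as the statistic (adjusted p = 0.0674). Of 12 checkpoint and regulatory genes, 1 rose (Cd274, which encodes PD-L1), 1 fell (Ido1) and 10 did not pass, with 2 rising and 1 falling when adjusted over the list alone. Cd274 had a log2 fold change of 0.83 in the authors' deposited table (adjusted p = 1.17e-05) and Ido1 one of -5.21 (adjusted p = 1.78e-06). Ido1 was little read, with a normalized count of 1.24 ± 1.37 (SD, n = 3) in D-Gel and 48.2 ± 21.5 (SD, n = 3) in L-Gel. The Toll-like receptor and NF-kB list shifted upwards (limma cameraPR, adjusted p = 0.0404): of 24 tested, 3 rose (Tnfaip3, Tlr7 and Tlr9), 0 fell and 21 did not pass, and 4 rose and 1 fell when adjusted over the list alone. That shift was lost in limma cameraPR with a preset correlation of 0.05 (adjusted p = 0.17) and with the log2 fold change as the statistic (adjusted p = 0.62). Without L-Gel library 3 the adjusted p of Tlr9 in the limma-trend refit was 0.0799, without L-Gel library 1 it was 0.0654 and without D-Gel library 3 it was 0.0598.

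Type I interferon genes, 24 tested, and interferon-gamma response genes, 19 tested, had 0 members past the threshold in the authors' DESeq2 table, with 1 member of each at an unadjusted p under 0.05. In the authors' deposited table, the landmark genes Adgre1 (log2 fold change -0.08, adjusted p = 0.86), Nos2 (0.11, adjusted p = 0.981), Arg1 (-1.88, adjusted p = 0.409), Mrc1 (-0.09, adjusted p = 0.938), Tnf (-0.07, adjusted p = 0.938), Il1b (-0.72, adjusted p = 0.499), Il6 (-1.01, adjusted p = 0.355), Il10 (-1.05, adjusted p = 0.0555), Cxcl9 (0.44, adjusted p = 0.906), Ccl5 (0.19, adjusted p = 0.781), Tlr2 (0.19, adjusted p = 0.556), Tlr4 (-0.02, adjusted p = 0.984), S100a8 (-0.73, adjusted p = 0.132), Gzmb (0.50, adjusted p = 0.701), Pdcd1 (-0.33, adjusted p = 0.891), Foxp3 (0.09, adjusted p = 0.986) and Adipoq (0.90, adjusted p = 0.633) did not pass. The implied 95% interval of the log2 fold change was -0.32 to 0.16 for Adgre1 in the authors' deposited table, and -4.03 to 0.28 for Arg1. Ly6g and Ifng were outside the authors' adjustment.

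Of 13 inflammatory macrophage genes 1 rose (Il1a) and 12 did not pass, and of 15 alternatively activated macrophage genes 2 rose (Ccl22 and Retnla) and 13 did not pass. Adjusted over the list alone, 3 inflammatory genes rose, and 3 alternative genes rose and 1 fell. Without L-Gel library 2 the adjusted p of Retnla in the limma-trend refit was 0.0514. Of 17 pro-inflammatory cytokines 1 rose (again Il1a) and 16 did not pass, with 3 rising when adjusted over the list alone. Without L-Gel library 2 the adjusted p of Il1a in the limma-trend refit was 0.0508. Of 9 type 2 genes 1 fell (Gata3) and 8 did not pass, with 1 rising and 3 falling when adjusted over the list alone. Of 13 inflammasome genes 1 rose (Naip2) and 12 did not pass, with 2 rising when adjusted over the list alone. The adjusted p of Naip2 in the limma-trend refit was 0.0511 without D-Gel library 2, 0.0521 without L-Gel library 1 and 0.0579 without L-Gel library 3. Of 12 neutrophil genes 1 rose (Mmp8), 1 fell (Ltf) and 10 did not pass, with 1 rising and 4 falling when adjusted over the list alone. Of 19 matrix protease and inhibitor genes 3 rose, 2 fell and 14 did not pass, with 4 rising and 4 falling when adjusted over the list alone. Mmp8 stands in both lists, its libraries overlapped between gels, and its adjusted p in the limma-trend refit was 0.0585 without D-Gel library 1, 0.0745 without D-Gel library 2, 0.0885 without L-Gel library 1 and 0.0548 without L-Gel library 2. Without D-Gel library 2 or without L-Gel library 2, 2 of the 5 picked protease and inhibitor genes rose and 1 fell, and without L-Gel library 3, 3 rose and 1 fell. The falling gene whose call was lost was Adam8, with an adjusted p in the limma-trend refit of 0.0726 without D-Gel library 2, 0.073 without L-Gel library 2 and 0.091 without L-Gel library 3. Of 4 eosinophil genes 1 rose (Siglecf), and of 9 mast cell genes 1 rose (Cpa3), with the same counts adjusted over the list alone. Without L-Gel library 3 the adjusted p of Cpa3 in the limma-trend refit was 0.0572, and without L-Gel library 2 it was 0.0535. Adipocyte (14 tested), glycolysis and hypoxia (18 tested) and dissociation stress (14 tested) genes each had 1 rising member (Pparg, Hk2 and Atf3) and no falling member, over all genes and adjusted over the list alone. The adipocyte list had a median log2 fold change of 0.58 and did not pass (limma cameraPR, adjusted p = 0.119), but passed upwards with ranks as the statistic (adjusted p = 0.0365). In the limma-trend refit, the adjusted p of Pparg was 0.0632 without D-Gel library 2, 0.0544 without D-Gel library 3, 0.0624 without L-Gel library 2 and 0.0804 without L-Gel library 3. That of Hk2 was 0.0536 without D-Gel library 1, 0.0644 without D-Gel library 2, 0.0773 without L-Gel library 1 and 0.0581 without L-Gel library 3. Schwann cell and neuron genes, 9 tested, had 1 rising (Mbp) and 1 falling (Tubb3), and 2 rising and 1 falling when adjusted over the list alone. Without L-Gel library 3 the adjusted p of Tubb3 in the limma-trend refit was 0.117, without L-Gel library 2 it was 0.122, without D-Gel library 1 it was 0.0878 and without D-Gel library 2 it was 0.052. Platelet genes, 6 tested, had 2 falling (Pf4 and Ppbp, both also in the chemokine list), with the same count adjusted over the list alone. Lymphatic endothelial (6 tested), red blood cell (7 tested) and mitochondrially encoded (12 tested) genes had 0 members past the authors' DESeq2 threshold and 0 at an unadjusted p under 0.05.

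**Figure D2:**
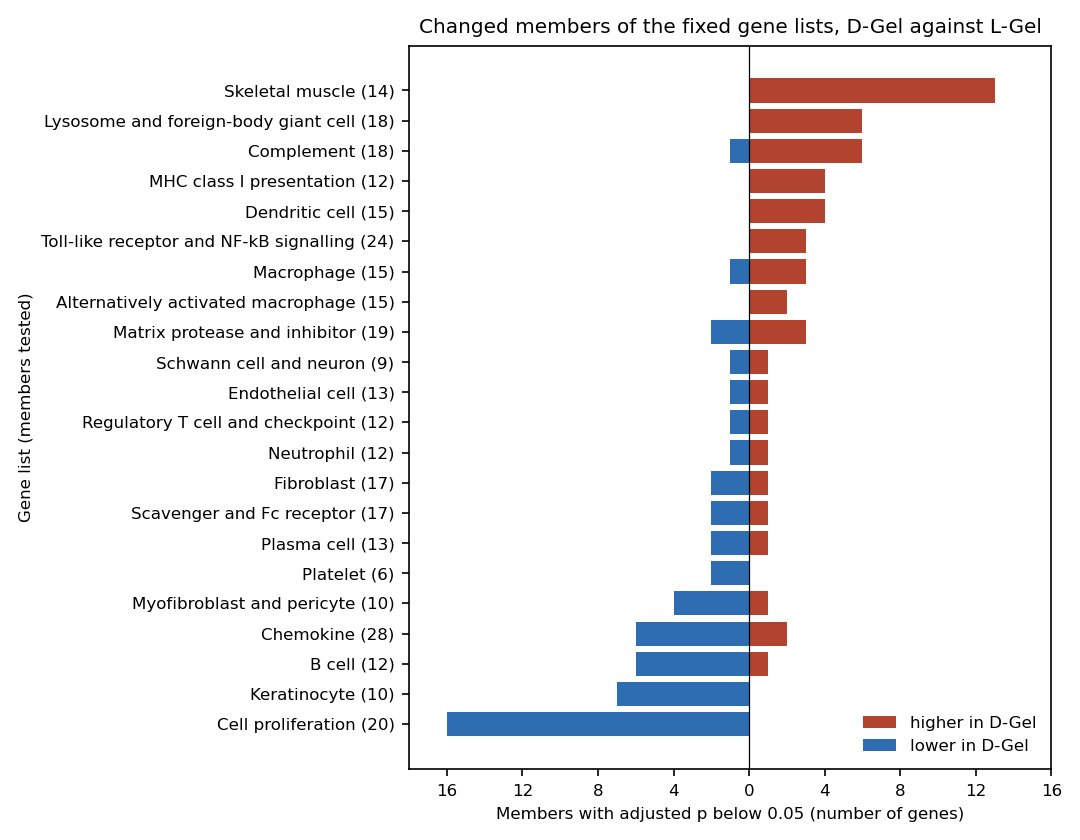
Number of members of each fixed list with an adjusted p under 0.05 in the authors' deposited table, higher in D-Gel (red, right) or lower in D-Gel (blue, left), for the lists with 2 or more such members. The number tested stands in brackets, and the skeletal muscle list had 13 higher members and the cell proliferation list 16 lower ones.

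Over the 38 fixed lists with at least 5 tested members, cameraPR found 9 shifted upwards and 5 downwards. With a correlation estimated from the values per library, which could be had for 15 lists, the skeletal muscle (adjusted p = 0.00665), MHC class I (adjusted p = 0.000354), keratinocyte (adjusted p = 2.39e-06) and cell proliferation lists (adjusted p = 0.0322) held in limma cameraPR. These adjusted p-values cover only those 15 lists. Whether the cell proliferation call (limma cameraPR, unadjusted p = 0.008585) would hold over 38 lists is not known. The MHC class I estimate came from only 3 of its 12 tested members. The class II, cytotoxic lymphocyte and Toll-like receptor lists had too few members with values for that estimate.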

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

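The adjustment over all 24034 genes with a p, the minimum fold of 0.5, and the list tests other than the estimated correlation were chosen after seeing the data. In that adjustment, genes outside the authors' own adjustment carried a p copied from the next tested row, which was not checked. The authors' calls were 657 higher and 596 lower; they became 194 and 299 with a log2 fold change of at least 1, 374 and 314 at an adjusted p under 0.01, 494 and 541 with a fold of at least 0.5, and 590 and 523 when readjusted over all genes. These alternatives accept fewer genes by construction. The limma-trend refit of the picked genes called 488 higher and 540 lower, 232 and 257 at an adjusted p under 0.01, and 189 and 308 with a log2 fold change of at least 1. Leaving out 1 library gave 352 to 462 higher and 355 to 533 lower genes; the lowest counts, 352 and 355, came without L-Gel library 3. Fewer libraries were tested there. The other pseudocounts, filters and tools stayed within 1.5 times, between 411 and 494 higher and between 386 and 541 lower.

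The fixed lists shifted, 9 upwards and 5 downwards, became 2 and 2 with an estimated correlation, adjusted over 15 lists in place of 38. All 5 downward lists had that estimate, but the upward class II, cytotoxic lymphocyte and Toll-like receptor lists did not. With the log2 fold change as the statistic the numbers were 1 upwards and 3 downwards, and the cause was not tested. A correlation of 0.05 gave 6 and 4, and ranks 9 and 4. With the replicate number as a block, limma-trend called 483 higher and 532 lower and edgeR 446 and 492. The numbers did not pair the libraries: deviations of same-numbered libraries correlated by 0.03, -0.06 and 0.10, and not every library correlated best with its own number. Of 74 named genes with values per library, 60 passed in every refit that tested them, 14 missed in at least 1, and 0 reversed. All 74 had been picked for their difference in these same libraries, so their passing is little evidence of robustness. TMM, upper-quartile and library-size scaling, fry, and camera with a block or without a library were not run, since the values covered only picked genes.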

Other observations

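The gene lists in the first 2 paragraphs, and the tests of upper epidermis genes, of muscle ratios, of the L-Gel library 1 excess and of luminal keratins, were chosen after the values or part of them had been seen. Several lysosomal hydrolase and lipid transporter genes rose: of 36 tested, 17 rose, 0 fell and 19 did not pass, and 25 rose when adjusted over the list alone. In the authors' deposited table, Naglu had a log2 fold change of 0.66 (adjusted p = 9.79e-08) and Gm2a, an activator of ganglioside breakdown, one of 0.81 (adjusted p = 0.00135). The list held in limma cameraPR (adjusted p = 1.24e-17, and adjusted p = 0.0176 with an estimated correlation). Of 14 non-classical MHC class I genes, 9 rose, 0 fell and 5 did not pass, with the same counts adjusted over the list alone (limma cameraPR, adjusted p = 3.6e-12, and adjusted p = 0.00884 with an estimated correlation). H2-Q6 had a log2 fold change of 1.09 in the authors' deposited table (adjusted p = 9.47e-10), and may share reads with its paralogs, which was not tested.

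Several genes of fatty acid use that are targets of PPAR receptors fell: of 17 tested, 6 fell, 0 rose and 11 did not pass, and 9 fell when adjusted over the list alone. The thioesterase gene Acot1 had a log2 fold change in the authors' deposited table of -2.32 (adjusted p = 2.39e-12) and Angptl4 one of -1.06 (adjusted p = 0.00015). The list held in limma cameraPR (adjusted p = 2.36e-09, and adjusted p = 0.00123 with an estimated correlation). Of 17 NRF2 targets, 3 fell (Hmox1, Akr1b8 and Gclm), 1 rose (Gstm1) and 13 did not pass, with the same counts adjusted over the list alone. Hmox1, which degrades heme, had a log2 fold change of -1.33 in the authors' deposited table (adjusted p = 1.28e-08). The NRF2 shift (limma cameraPR, adjusted p = 0.0067) was lost (adjusted p = 0.225 with an estimated correlation).

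Several epithelial genes, such as Krt8 and Krt14, were read in L-Gel and were at or near 0 in D-Gel. If epidermis had come with the L-Gel tissue, upper epidermis genes would have fallen with Krt14. The 4 tested had a median log2 fold change of 0.514 and 0 passed downwards, which argues against it for these 4 genes. Outside the test, Lgals7 of the keratinocyte list fell (log2 fold change -6.63 in the authors' deposited table, adjusted p = 8.68e-07). So did Sprr1a, a gene of the cornified envelope (-4.59 in the limma-trend refit, adjusted p = 0.000759). Mammary gland tissue may be another source and stays open. The 11 tested mammary genes had a median log2 fold change of -1.049, and 1, Grhl2, fell past the threshold. That share of 9.09% met the bound set beforehand against this source. Its exact 95% interval, added after the share was seen, ran from 0.23% to 41.3%. The list was meant for genes not yet looked at. It left out the milk protein gene Csn3, already seen to fall (log2 fold change -8.62 in the authors' deposited table, adjusted p = 3.14e-13). Outside the list too, Elf5 had a log2 fold change of -4.63 (adjusted p = 0.000742) in the limma-trend refit. The prolactin receptor gene Prlr had one of -4.22 there (adjusted p = 0.00133). They are named because they fell, so they cannot decide the question. Adjusted over the list alone 5 of the 11 fell and 1 rose, and the list shifted downwards (limma cameraPR, adjusted p = 0.013), which goes with this source. Its correlation could not be estimated, and the preset 0.01 was used. The riser, Xdh, had been seen before the list was written, and an effect of the gel on epithelium stays open and untested.

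Skeletal muscle genes were higher in D-Gel, by far the least in D-Gel library 1. Whether 1 source of muscle RNA was present in different amounts stays open: over 13 called genes, which are not independent replicates, the log2 ratio to D-Gel library 1 had an SD of 0.943 (median 3.97, rank correlation across genes 0.70) for library 2 and of 1.08 (median 4.11, rank correlation 0.69) for library 3, between the bounds for and against it. Regenerating fibres could also contribute: the 11 tested regeneration genes had a median log2 fold change of 5.445, and 1 passed upwards (Myh8, seen before the list was written), 9.09% with an exact 95% interval from 0.23% to 41.3%. Adjusted over the list alone 6 of the 11 rose, and the list shifted upwards (limma cameraPR, adjusted p = 8.32e-05). Both can hold together, and whether the gel changed the muscle or the sampling differed cannot be told apart.

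Cell proliferation genes were lower in D-Gel, at a median of 52.7% of their L-Gel mean; if dividing B cells or basal epithelial cells carried the excess in L-Gel, it would scale with their markers. The excess of L-Gel library 1 relative to the mean of libraries 2 and 3 was 0.455 (quartiles 0.384 and 0.51) over 16 proliferation genes, under the bound of 0.5 set for it, but 0.197 over 10 B-cell and basal keratin genes and 0.73 over all 541 lower genes, and it rests on 1 library. The bound alone would have favoured this source; the comparison with the markers, added after the value was seen, leaves it open. The same excess was 1.26 over Krt8, Krt18 and Epcam, which goes against dividing luminal epithelial cells, but it rests on the same library, and these genes differed by at most 1.611-fold between L-Gel libraries, so this source stays open. An effect of the gel on dividing immune or stromal cells stays open and untested.

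The refit of the picked genes called 1028 of them in the real split of the 6 libraries. Of the 10 possible splits, 1 called as many, the real one, and the highest other called 3. The genes had been picked for this split, and 10 splits are too few for a share under 0.05.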
